A study of Homo sapiens with 11 samples.

How the data were processed

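RNA expression was measured in Reh cells, an established B-cell precursor leukaemia line that carries the ETV6-RUNX1 fusion. All cells profiled stably expressed miR-125b. They were transfected with precursor oligonucleotides of scrambled sequence, of miR-99a, of miR-100, or of both. The labels give 66 µM for the scrambled oligo and for each single oligo, and 33 µM of each in the combination, so that the total was equal. Transfections were 72 h apart and the cells were harvested 48 h after the last of them. The labels give 2 control arrays and 3 arrays for each of the 3 treatments, 11 in all, and do not say whether replicates were separate cultures, so some may be technical.

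The samples were hybridized to Affymetrix human whole-genome expression arrays after labelling with the maker's one-cycle kits. The values deposited by the authors are on a log2 scale, read from their range of 4.398 to 14.839. The medians of the 11 arrays lie between 5.95 and 5.984 while the distributions are not identical, so the deposited values had been scaled between arrays but not by a plain quantile step at the end. How the probe sets were summarised, the background step and the normalization method are not given in the sources used here. Such a step can leave differences between arrays at high intensity, which is why quantile normalization was tried.

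The table holds 54675 probe sets. Of these, 62 are control probe sets of the array, and they entered no comparison of genes. A gene was listed for 42898 probe sets. The 1801 probe sets listed with several genes and the 11777 without a gene were left out. Any control probe sets listed with a gene, and any entries without a symbol, were dropped too, which left 41091. Gene identifiers of 41037 probe sets matched the RefSeq gene table (human, GRCh38.p14) and 54 did not. Each gene was represented by its probe set with the highest mean over all arrays, giving 19775 genes, of which 9252 had 1 probe set and 10523 had several. No filter on dim genes was applied. Across 1687 genes with a mean above 8 and several probe sets, the median correlation between probe sets of the same gene was 0.849.

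Groups were compared with limma 3.58.1 in R 4.3.3. A mean per group was fitted over all 11 arrays with lmFit and moderated with eBayes, so that the control group shared the estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over all genes within a comparison, and genes with an adjusted p under 0.05 were called. All p-values are 2-sided unless stated otherwise. The 6 comparisons were miR-99a, miR-100, the combination, and the mean of all treatments, each against control, then miR-100 against miR-99a, and the combination against the mean of the single oligos. Because 3 comparisons with a treatment share the control arrays, the likeness of the treatments was set against 100 simulated sets of unchanged groups compared with the same control arrays.

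A total of 28 gene lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry, a rotation test of the list on its own. The lists cover reported and predicted miR-99/100 targets, reported miR-125b targets, the mTOR and PI3K pathway, the glucocorticoid response, tubulin and microtubule genes, ABC drug transporters, the mitotic cell cycle, DNA replication, the BCL2 family, p53 targets, the type I interferon response, cholesterol synthesis, the ATF4 and unfolded protein response, the NF-kB and TNF response, and glycolysis and hypoxia. They also cover cytoplasmic and mitochondrial ribosomal proteins, oxidative phosphorylation, the microRNA machinery, heat shock proteins, the proteasome, replication-dependent histones, B-lineage markers, and markers of T and NK cells, myeloid cells, erythroid cells and platelets, and fibroblasts and epithelium. They were written from general knowledge, so the target lists are neither complete nor tested for sites.

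The comparisons, lists, tests, alternatives and the rule for naming genes were fixed before the data were examined, apart from those named as chosen later. The rule named, in each comparison with control, the 10 largest called rises and falls with no overlap between the groups' arrays, or the 5 smallest p-values in each direction where none passed, and 5 each way in the other comparisons. It always named a fixed set of reported targets and of genes related to vincristine. From each list it named up to 4 members that passed, or the 2 with the smallest p. Genes outside the rule are said to be chosen after their values were seen.

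The replicate number in the labels was tested as a pairing. After removing group means, arrays of different treatments with the same number correlated across genes in 9 of 9 pairs (r 0.168 to 0.816), above the minimum of 0.1 set for a pairing. Pairs of a control and a treated array with the same number correlated at -0.152 to 0.438. By this range the numbers pair the treated groups but not clearly the control. Control replicate 1 correlated at -0.146, -0.019 and -0.152 with replicate 1 of miR-99a, miR-100 and the combination. Its values were lower with replicate 2 (-0.438, -0.148 and -0.345) and higher with replicate 3 (0.365, 0.106 and 0.329). The group means removed include replicate 3 in the treatments only, so a pairing of the control is not excluded. Most of the pairing of the treated groups is replicate 3 against the rest. Treated arrays of replicates 1 and 2 with different numbers correlated at 0.358 to 0.423, above some pairs with the same number. The fit with the replicate number as a block is therefore given beside the results whose call it changed, and beside others that it moved.

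Fits added after the principal components were seen had replicate 3 as a term, or used the arrays of replicates 1 and 2 alone. The control has no replicate 3, so in both the treatments are compared with control through replicates 1 and 2, and the condition of no overlap was applied to those arrays. The term was also tried together with quantile normalization. The other fits were quantile normalization, centring, a filter at the median level, the mean of all probe sets of a gene, leaving out probe sets that match several transcripts, eBayes with trend and robust, the compared groups alone, a 2-fold minimum, limma's treat against 1.2-fold, and leaving out each array.

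The test was tried on simulated data with 200 changed genes in each of 20 sets. For the combination against control it found 4.93% of genes changed 1.2-fold, 68.5% of those changed 1.5-fold and 91.2% of those changed 2-fold. For all treatments against control, a shift of -0.1 log2 put on the proteasome list was found in 14 of 20 sets by camera. These simulated values had independent noise for each gene and no replicate 3 difference, so the rates need not hold for the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A search for seed sites was not made, because the reference used here holds no 3' UTR sequences. Cells stably expressing a scrambled microRNA and a vincristine viability assay are also named in the description and were not analysed here.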

Results

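The data are 11 whole-genome expression profiles of Reh leukaemia cells that stably express miR-125b. Of these, 2 had received a scrambled oligo, 3 miR-99a, 3 miR-100 and 3 both oligos. Values are log2 expression, and 19775 genes were measured. Among genes of immature B cells, DNTT, the template-independent DNA polymerase of immature lymphocytes, had a mean of 13.09 ± 0.03 in control (SD, n = 2), and the surrogate light chain gene IGLL1 and the transcription factor gene PAX5 stood at 12.26 ± 0.17 and 11.58 ± 0.09. Not every B-lineage marker was high, with VPREB1 at 5.5 ± 0.03 and IKZF3 at 5.69 ± 0.02. As examples of other lineages, the T-cell gene CD3D stood at 5.8 ± 0.17 and the myeloid gene LYZ at 5.39 ± 0.05. The array medians were 5.95 to 5.984. Probe sets differ in affinity, so these levels do not rank the genes by amount and the lineage of the cells was not tested.

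Arrays were alike, with correlations of 0.989 to 0.998 over 55 pairs, yet the arrays numbered replicate 3 stood apart in every treatment. Replicate 3 arrays of different treatments correlated at 0.998 with each other and at 0.991 to 0.992 with replicates 1 and 2 of their own treatment. The first principal component, with 53.2% of the variance against 13.6% for the next, placed replicate 3 between -21.4 and -18 and the other treated arrays between 7.78 and 12.4. The control arrays, at -3.42 and 2.12, lay between them. In the treated arrays 5794 genes (29.3%) differed between replicate 3 and the others. Oxidative phosphorylation and ribosomal protein genes were lower in replicate 3 and mitotic genes higher (median log2 differences -0.53, -0.282 and 0.336, adjusted p 1.47e-20, 2.55e-11 and 1.1e-07, each with adjusted p = 0.789 with an estimated correlation).

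**Figure D1:**
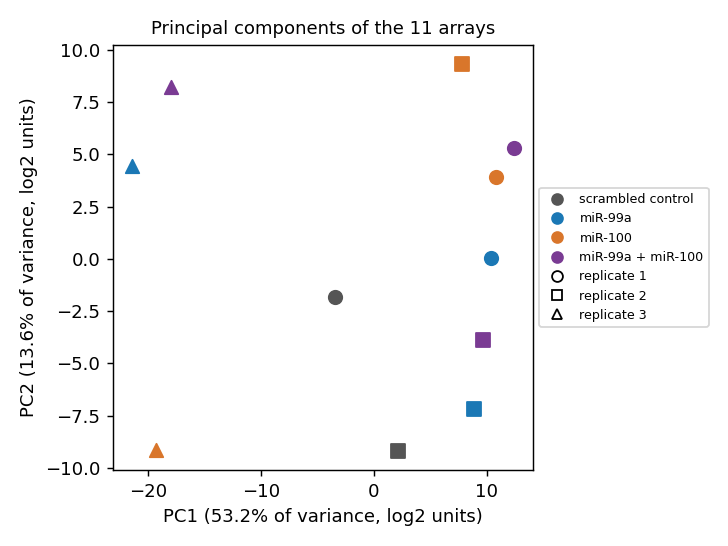
Principal components of the 11 arrays, with the first component (53.2% of the variance) on the horizontal axis and the next (13.6%) on the vertical axis; colour gives the group and shape the replicate number. The 3 replicate 3 arrays lie between -21.4 and -18 on the first component, and the 2 control arrays lie between them and the other treated arrays.

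The first question was whether messenger RNAs reported as targets of miR-99 and miR-100, microRNAs of the same seed family, were lower after transfection. FKBP5, a co-chaperone of the glucocorticoid receptor, was the nearest to a fall in the fit without a block. Its log2 difference from control was -0.15 ± 0.09 with miR-99a, -0.15 ± 0.09 with miR-100 and -0.17 ± 0.09 with both (SE, n = 3 against 2). In each treatment all its arrays lay below both control arrays. Arrays did not overlap, in either direction, in 15.4%, 13.4% and 20.5% of all genes, against 20% by chance. Genes of every kind with a mean of 10 to 12, the level of FKBP5, had medians of -0.068, -0.079 and -0.066. MTOR (-0.03 ± 0.16, 0.01 ± 0.16 and -0.03 ± 0.16) and its partner RPTOR (0.02 ± 0.1, -0.05 ± 0.1 and -0.03 ± 0.1) had group means close to control. The chromatin remodeller SMARCA5 had -0.08, -0.11 and -0.17 (SE 0.14) and the receptor BMPR2 had -0.11, -0.08 and -0.11 (SE 0.09), whereas BAZ2A had 0.17, 0.08 and 0.12 (SE 0.07). IGF1R, SMARCD1, CTDSPL, TRIB2 and AGO2 lay between -0.07 and 0.09. None of these genes passed the test over all arrays. Several of the values depend on replicate 3, which has no control array of its number: MTOR was 6.86 to 6.92 in replicates 1 and 2 of the treatments, 7.17 to 7.36 in replicate 3, and 7.07 and 6.99 in control. Fitted with the replicate block, FKBP5 had -0.15, -0.16 and -0.17 (adjusted p 0.592, 0.463 and 0.304), MTOR had -0.15 ± 0.09, -0.11 ± 0.09 and -0.16 ± 0.09 (adjusted p 0.566, 0.633 and 0.328) and BMPR2 -0.13, -0.1 and -0.13 (adjusted p 0.67, 0.727 and 0.481). SMARCA5 had -0.19, -0.21 and -0.28 (SE 0.09, adjusted p 0.445, 0.27 and 0.0451) with the block, so it passed with both oligos in that fit alone, and its adjusted p was 0.0642 with replicate 3 as a term. The 95% intervals for MTOR with both oligos, -0.39 to 0.32, and for FKBP5, -0.36 to 0.03, leave room for small falls.

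As a group, the 18 measured reported targets were not called, with median log2 differences of 0.015, -0.015 and -0.02 for miR-99a, miR-100 and both (adjusted p 0.339, 0.783 and 0.828). The miR-100 median was -0.125 without miR-100 replicate 3, and with the replicate block the medians were -0.003, -0.074 and -0.054 (adjusted p 0.978, 0.329 and 0.538). The 31 predicted targets were lower by camera in each treatment, with medians of -0.075, -0.088 and -0.036 (adjusted p 0.0183, 0.0333 and 0.0324). With an estimated correlation none held (adjusted p = 0.816, 0.763 and 0.936). Genes of every kind with a mean of 8 to 10 had medians of -0.041, -0.058 and -0.079, and those of 6 to 8 had 0.007, 0 and -0.006. No member of the predicted list passed alone. PPM1D, a phosphatase of the p53 pathway, had -0.16 ± 0.09 with miR-99a, RMND5A -0.18 ± 0.09 with miR-100, and AP1AR and KBTBD8 -0.25 ± 0.09 and -0.29 ± 0.1 with both. With the replicate number as a block the medians were no smaller for miR-100 and both, at -0.073, -0.102 and -0.063, but the calls ended (adjusted p 0.0948, 0.111 and 0.179). Quantile normalization reduced the medians to -0.044, -0.028 and -0.016 and ended the calls (adjusted p 0.0906, 0.39 and 0.48), and among genes at or above the median level those of miR-99a and both ended with medians of -0.09 and -0.1 (0.0976 and 0.101). They also ended when control replicate 1 was left out, with medians of -0.041, -0.066 and -0.037 (adjusted p 0.124, 0.158 and 0.211), so that with both oligos the shift itself did not shrink. For miR-99a and miR-100 they ended too without miR-99a replicate 3 (-0.062, 0.0984) and miR-100 replicate 2 (-0.039, 0.161). Over all refits without 1 array the medians lay between -0.082 and -0.041 for miR-99a, -0.155 and -0.039 for miR-100, and -0.079 and -0.036 for both. In replicates 1 and 2 alone the miR-100 call held (median -0.155, adjusted p 0.0412, and 0.605 with an estimated correlation), while those of miR-99a (-0.062, 0.126) and both (-0.051, 0.33) ended.

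**Figure D2:**
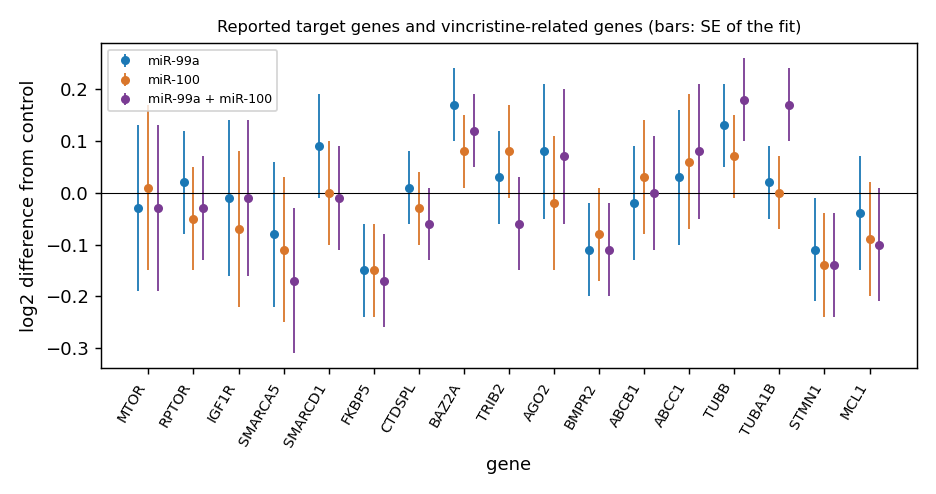
Log2 difference from control, with its standard error, of 17 reported target genes and genes related to vincristine under each treatment (n = 3 against 2 arrays). FKBP5 lies at -0.15, -0.15 and -0.17, and no gene shown passed the test.

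The study concerns resistance to vincristine, a drug that binds tubulin and is exported by ABC transporters. ABCB1, the gene for P-glycoprotein, had log2 differences of -0.02, 0.03 and 0 from control (SE 0.11), and ABCC1 had 0.03, 0.06 and 0.08 (SE 0.13). ABCB4, a phospholipid transporter gene, had 0.25 ± 0.07 with miR-99a, 0.13 ± 0.07 with miR-100 and 0.27 ± 0.07 with both. It was the 1 member of the list of 12 ABC transporters that passed when adjusted over the list alone, with both oligos, and none passed over all genes tested. Its level, 5.33 in control, was below the arrays' median. The beta-tubulin gene TUBB had 0.13, 0.07 and 0.18 (SE 0.08) and the alpha-tubulin gene TUBA1B 0.02, 0 and 0.17 (SE 0.07). STMN1, whose product destabilises microtubules, had -0.11, -0.14 and -0.14 (SE 0.1), and the survival gene MCL1 had -0.04, -0.09 and -0.1 (SE 0.11). Over all arrays, without a block, neither the ABC transporters (medians 0.036, 0.044 and 0.032, adjusted p 0.0635, 0.117 and 0.224) nor the 37 tubulin and microtubule genes (0.022, 0.004 and 0.017, adjusted p 0.128, 0.384 and 0.357) were called as a group. After quantile normalization camera called the tubulin list upward with miR-99a (median 0.046, adjusted p 0.01) and miR-100 (0.048, 0.0275) but not with both (0.071, 0.104), and with an estimated correlation the adjusted p was 0.853 and 0.987. With miR-99a it was also called among genes at or above the median level (0.014, 0.0499) and without miR-99a replicate 2 (0.026, 0.0479), and with both oligos without combination replicate 1 (0.063, 0.036), with adjusted p = 0.931, 0.81 and 0.958 with an estimated correlation. The replicate block turned its medians to -0.026, -0.044 and -0.044 (adjusted p 0.828, 0.314 and 0.582). The ABC transporters had 0.052, 0.052 and 0.057 after quantile normalization (adjusted p 0.0906, 0.211 and 0.16) and were called with miR-99a only without miR-99a replicate 2 (0.023, 0.026, and 0.81 with an estimated correlation). Over all treatments camera called them without miR-99a replicate 2 (0.029, 0.0483) and without combination replicate 2 (0.043, 0.0336). With an estimated correlation these had adjusted p = 0.744 and 0.649.

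In cells given miR-99a, genes of the proteasome, the complex that degrades tagged proteins, were lower than in control in 26 of 27 cases, with a median log2 difference of -0.116 (n = 3 against 2). PSMB3 had -0.19 ± 0.11 and PSMD12 -0.17 ± 0.1. Mitochondrial ribosomal protein genes were lower in 63 of 72 cases (median -0.081), among them MRPL3 at -0.21 ± 0.1 and MRPL48 at -0.19 ± 0.1. Oxidative phosphorylation genes (54 of 59, median -0.074) and cytoplasmic ribosomal protein genes (45 of 53, median -0.033) were lower too, with NDUFA9 at -0.22 ± 0.12, COX4I1 at -0.14 ± 0.1, RPL27A at -0.36 ± 0.12 and RPLP2 at -0.21 ± 0.08. Camera's adjusted p was 0.000715 for the proteasome and for the mitochondrial ribosome, 0.0404 and 0.0208 for the others, and each list had adjusted p = 0.816 with an estimated correlation. Genes of every kind with a mean of 8 to 10 had a median of -0.041, and those of 10 to 12 had -0.068. At 13 or more, the 49 genes that are not ribosomal protein genes had -0.034. The oxidative phosphorylation and cytoplasmic ribosomal medians were therefore close to those of other genes of their level. With the replicate block the proteasome kept its call (adjusted p 0.000165) and the mitochondrial ribosome lost it (median -0.033, 0.628). With replicate 3 as a term in place of the block, 0 lists passed with an estimated correlation. Oxidative phosphorylation turned upward with the block (median 0.102, adjusted p 0.00278, and 0.992 with an estimated correlation) and the cytoplasmic ribosome had 0.066 (adjusted p 0.0831). The block also called mitotic genes (median -0.172, adjusted p 1.09e-09), DNA replication genes (-0.107, 5.43e-05) and the microRNA machinery (-0.115, 0.000562) downward and histones (0.068, 0.0366) upward, each with adjusted p = 0.992 with an estimated correlation. Leaving out control replicate 2 ended the calls of the proteasome (median -0.074, adjusted p 0.0647), the mitochondrial ribosome (-0.039, 0.195), the cytoplasmic ribosome (0.011, 0.478) and oxidative phosphorylation (0.035, 0.979), and leaving out miR-99a replicate 3 ended those of the last 3 (0.011 and 0.943, 0.004 and 0.246, 0.129 and 0.168). Oxidative phosphorylation also lost its call without miR-100 replicate 3, at an unchanged median of -0.074 (0.0651). At the other end, leaving out 1 array took the medians to -0.165, -0.142, -0.073 and -0.187 for the proteasome, the mitochondrial ribosome, the cytoplasmic ribosome and oxidative phosphorylation. Quantile normalization ended the calls of the proteasome (median -0.054, adjusted p 0.124), the mitochondrial ribosome (-0.047, 0.102) and oxidative phosphorylation (-0.02, 0.772). Among genes at or above the median level oxidative phosphorylation (median unchanged at -0.074, adjusted p 0.197) and the cytoplasmic ribosome (-0.028, 0.239) were not called.

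No single gene passed limma's test with miR-99a, while 198 genes had an unadjusted p under 0.05 and the lowest adjusted p was 0.9998. The smallest p-values upward were those of PTK2B, a focal adhesion tyrosine kinase (log2 difference 0.28 ± 0.06), the splicing factor PRPF6 (0.46 ± 0.13), ABCB4, HSPA2-AS1 (0.23) and CABP1 (0.22). Downward they were CARNMT1 (-0.33 ± 0.08), LINC00314 (-0.29), the noncoding RNA GAS5 (-0.24 ± 0.06), SLC25A43 (-0.24) and FBXO5, an inhibitor of the anaphase-promoting complex (-0.24 ± 0.07). The groups' arrays did not overlap in 3051 genes, 15.4% against 20% expected by chance. The 198 genes with an unadjusted p under 0.05 were also fewer than chance gives, which is 0.05 of 19775. With the replicate block 1981 genes had such a p. The 0 calls without a block therefore do not show that nothing changed. The replicate block called 5 genes: RBM42 (0.46, against 0.28 without a block), S1PR4 (0.44 against 0.21), SAMD1 (0.45 against 0.27) and SF3A2 (0.45 against 0.24) upward and ZNF91 (-0.52 against -0.46, adjusted p 0.00148) downward. These 5 were named after their values were seen, and with replicate 3 as a term 0 genes passed. S1PR4 (-0.67) and SF3A2 (-0.62) are among the genes that set replicate 3 apart from replicates 1 and 2.

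With miR-100 all 27 proteasome genes were lower than in control (median log2 difference -0.111, n = 3 against 2), with PSMD12 at -0.25 ± 0.1 and PSMD14 at -0.26 ± 0.13. Mitochondrial ribosomal protein genes were lower in 60 of 72 cases (median -0.094), with MRPL3 at -0.28 ± 0.1. Genes of the microRNA machinery, which processes and uses microRNAs, were lower in 19 of 22 cases (median -0.096), with CNOT7 at -0.2 ± 0.1 and PRKRA at -0.16 ± 0.1. The ATF4 and unfolded protein response (23 of 32, median -0.072) included PDIA6 at -0.18 ± 0.08 and MTHFD2 at -0.2 ± 0.1. Among cytoplasmic ribosomal protein genes (36 of 53 lower, median -0.021), RPLP2 at -0.38 ± 0.08 was the 1 gene past the threshold adjusted over the list alone, and its probe set was dim, at 6.09 in control. Camera's adjusted p was 6.35e-05, 6.8e-05, 0.0109, 0.0399 and 0.0399 in that order, and each list had adjusted p = 0.763 with an estimated correlation. Genes of every kind with a mean of 8 to 10 had a median of -0.058, and those of 10 to 12 had -0.079. At 13 or more, the 49 genes that are not ribosomal protein genes had -0.012. Part of each list's shift was therefore shared with other genes of its level. With the replicate block the cytoplasmic ribosome turned upward (median 0.072, adjusted p 0.0415, and 0.94 with an estimated correlation) and the mitochondrial ribosome lost its call (median -0.052, 0.305). The block also called mitotic genes (median -0.158, adjusted p 1.74e-08), DNA replication genes (-0.111, 7e-05) and interferon response genes (-0.081, 0.00286) downward and oxidative phosphorylation upward (0.138, 5.17e-05), each with adjusted p = 0.892 with an estimated correlation. Leaving out miR-100 replicate 2 ended the calls of the proteasome (median -0.074, adjusted p 0.102), the mitochondrial ribosome (-0.053, 0.102), the microRNA machinery (-0.023, 0.341) and the unfolded protein response (-0.047, 0.194). Leaving out control replicate 2 ended those of the mitochondrial ribosome (-0.045, 0.0916), the microRNA machinery (-0.061, 0.165), the unfolded protein response (-0.046, 0.88) and the cytoplasmic ribosome (0.018, 0.741). Leaving out miR-100 replicate 1 ended those of the microRNA machinery (-0.025, 0.251) and the unfolded protein response (-0.016, 0.64), and leaving out miR-100 replicate 3 that of the cytoplasmic ribosome (0.072, 0.181). The lowest medians without 1 array were -0.202 for the proteasome, -0.137 for the mitochondrial ribosome, -0.19 for the microRNA machinery, -0.144 for the unfolded protein response and -0.078 for the cytoplasmic ribosome. Quantile normalization reduced the proteasome median to -0.041 (adjusted p 0.0275) and ended the calls of the mitochondrial ribosome (-0.025, 0.209), the microRNA machinery (-0.022, 0.556) and the unfolded protein response (-0.004, 0.923). Among genes at or above the median level the microRNA machinery (median unchanged at -0.096, adjusted p 0.12), the unfolded protein response (-0.075, 0.436) and the cytoplasmic ribosome (-0.015, 0.874) were not called.

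For miR-100 limma called 0 genes, with 305 at an unadjusted p under 0.05 and a lowest adjusted p of 1. The smallest p-values downward belonged to RPLP2, the histone gene H3-3A (-0.48 ± 0.11), DSPP (-0.38), the mitochondrially encoded complex I subunit ND6 (-0.5 ± 0.13) and the axonemal dynein gene DNAH3 (-0.5 ± 0.13). Upward they were GTF2I-AS1 (0.25), DIRC1 (0.27), PANX3 (0.29), ENAM (0.24) and BMP1 (0.24). DIRC1, PANX3 and ENAM lay below the arrays' median level. The groups' arrays did not overlap in 2643 genes, 13.4% against 20% by chance. The 305 genes with an unadjusted p under 0.05 were again below the share of 0.05 expected by chance. With the replicate block 2502 genes had such a p. The replicate block called 7 genes, named after their values were seen: HMGA1 (0.44, against 0.17 without a block) and S1PR4 (0.43 against 0.21) were higher, and ZNF91 (-0.55 against -0.49, adjusted p 0.000435), CENPE (-0.45 against -0.15), DNAH3 (-0.42 against -0.5), H3-3A (-0.41 against -0.48) and ND6 (-0.41 against -0.5) were lower. With replicate 3 as a term 0 genes passed, and HMGA1 (-0.8), S1PR4 (-0.67) and CENPE (0.92) are among the genes that set replicate 3 apart from replicates 1 and 2.

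With both oligos, cytoplasmic ribosomal protein genes were higher than in control in 48 of 53 cases, with a median log2 difference of 0.199 and a group mean of 13.45 ± 0.21 against 13.3 ± 0.05 in control (SD, n = 3 and 2), while the dim probe sets of RPLP2 and RPL27A had -0.35 ± 0.08 and -0.49 ± 0.12. All 27 proteasome genes were lower (median -0.124, group mean 10.66 ± 0.06 against 10.8 ± 0.04), with PSMD12 at -0.31 ± 0.1 and PSMC6 at -0.37 ± 0.15. Lower too were DNA replication genes (31 of 36, median -0.079), with the replication factor RFC3 at -0.29 ± 0.07 and CCNE1 at -0.19 ± 0.08, and mitotic genes (28 of 34, median -0.099), with CCNA2 at -0.25 ± 0.11 and TTK at -0.23 ± 0.15. Mitochondrial ribosomal protein genes (60 of 72, median -0.091) included MRPL48 at -0.29 ± 0.1, and the microRNA machinery (16 of 22, median -0.108) included PRKRA at -0.22 ± 0.1 and AGO3 at -0.2 ± 0.11. Camera's adjusted p was 4.87e-09, 5.92e-05, 0.0105, 0.0225, 6.39e-06 and 0.0121 in the order given, and each list had adjusted p = 0.936 with an estimated correlation. Genes of every kind with a mean of 8 to 10 had a median of -0.079, and those of 10 to 12 had -0.066. At 13 or more, the 49 genes that are not ribosomal protein genes had 0.146. The DNA replication median was therefore that of genes of its level, and part of each other shift was shared in the same way. After quantile normalization, which sets this bright list to nearly the same level on every array, the ribosomal protein median was -0.011 (adjusted p 0.114). That step also ended the calls of mitotic genes (median -0.043, adjusted p 0.606), DNA replication (-0.023, 0.204), the mitochondrial ribosome (-0.029, 0.104) and the microRNA machinery (-0.032, 0.472), and left the proteasome at -0.097 (0.00571). Among genes at or above the median level mitotic genes (adjusted p 0.325), DNA replication (0.22) and the microRNA machinery (0.211) were not called, at unchanged medians of -0.099, -0.079 and -0.108, and glycolysis and hypoxia genes were called upward (0.023, 0.00538, and 0.921 with an estimated correlation). Leaving out 1 array moved the ribosomal protein median between 0.113, without combination replicate 2, and 0.332, without combination replicate 3. The proteasome moved between -0.183 and -0.075 and the mitochondrial ribosome between -0.145 and -0.034, and both kept their calls in 11 of 11 refits (highest adjusted p 0.00731, without control replicate 2, and 0.0281, without combination replicate 3). The ranges were -0.206 to -0.068 for mitotic genes, -0.139 to -0.023 for DNA replication and -0.119 to -0.055 for the microRNA machinery. Under the replicate block the mitochondrial ribosome kept its median, at -0.093, and lost its call (adjusted p 0.179), while the medians of mitotic genes (-0.226, 2.64e-10) and DNA replication (-0.159, 5.43e-07) were larger, each with adjusted p = 0.784 with an estimated correlation. The block called oxidative phosphorylation upward (median 0.176, adjusted p 1.92e-08) and interferon response genes downward (-0.13, 0.00317), each with adjusted p = 0.784 with an estimated correlation. The mitotic call ended without control replicate 1 (median -0.068, adjusted p 0.454), combination replicate 1 (-0.068, 0.395) or combination replicate 2 (-0.071, 0.123). That of DNA replication ended without control replicate 2 (-0.023, 0.313) or combination replicate 1 (-0.029, 0.348), that of the microRNA machinery without the same arrays (-0.055, 0.114 and -0.065, 0.129), and that of the predicted targets also without combination replicate 3 (-0.051, 0.21).

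At the level of genes limma called 0 with both oligos, with 724 at an unadjusted p under 0.05 and a lowest adjusted p of 0.9998. The smallest p-values were those of PPFIBP1, a liprin family gene (log2 difference -0.49 ± 0.09), the chromatin subunit gene ACTL6A (-0.36 ± 0.07), the cap methyltransferase gene CMTR2 (-0.36 ± 0.08), FBXO5 (-0.32 ± 0.07) and EMP1 (-0.49 ± 0.11) downward. Upward they were ENAM (0.34 ± 0.07), PTK2B (0.27 ± 0.06), LACC1 (0.34 ± 0.08), DIRC1 (0.31) and WFIKKN2 (0.25). The arrays did not overlap in 4047 genes, 20.5% against 20% by chance. The 724 genes with an unadjusted p under 0.05 were fewer than the share of 0.05 expected by chance. With the replicate block 3534 genes had such a p.

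More genes were called for both oligos once the difference of replicate 3 was taken out. With replicate 3 as a term, 160 genes rose and 283 fell against control, 443 in all. Of these, 253 were also called, in the same direction, among the 290 genes found in replicates 1 and 2 alone. Both fits use the same control arrays and combination replicates 1 and 2, so this overlap is not independent support. The balance of directions was not stable: those 290 were 182 up and 108 down, and the term with quantile normalization gave 426 up and 174 down. The replicate block gave 286 up and 577 down, 863 in all. The largest rises with the term were those of PPP3R1, the regulatory subunit of calcineurin (0.61 ± 0.17), PPDPF (0.53 ± 0.09), IGFBP2, an insulin-like growth factor binding protein (0.51 ± 0.12), ZFAS1 and HCFC1R1 (0.49 each), CHCHD10 and JDP2 (0.48 each), NAT14 and BBLN (0.47 each) and MARCKSL1 (0.46). The largest falls were those of the zinc finger gene ZNF91 (-0.53 ± 0.13), the kinetochore motor gene CENPE (-0.52 ± 0.14), UTP15 and PPFIBP1 (-0.49 each), the helicase gene RECQL and TWF1 (-0.48 each), EMP1, ZNF765 and FAM111B (-0.47 each) and PPHLN1 (-0.46). In the lists, counting only called genes here and in what follows, 26 cytoplasmic ribosomal protein genes rose and 2 fell of 53. Adjusted over the list alone these were 37 and 2. Among the rises were RPL38 at 0.43 and RPL31 and RPS15A at 0.41. Of 59 oxidative phosphorylation genes 8 rose and 1 fell (23 and 4 over the list alone), with ATP5F1E at 0.44 and COX7B at 0.42. Mitotic genes fell in 7 of 34 cases (18), with DLGAP5 at -0.4 and HMMR at -0.37, DNA replication genes in 5 of 36 (9), with CDC6 at -0.41 and RRM1 at -0.35, and proteasome genes in 5 of 27 (11), with PSMC3 at -0.36 and PSMB7 at -0.34. By camera these lists had adjusted p 7.78e-25, 6.97e-08, 1.24e-08, 1.5e-06 and 2.18e-05, and all had adjusted p = 0.76 with an estimated correlation. The mitotic, replication, oxidative phosphorylation and ribosomal lists are among those that set replicate 3 apart, in the opposite direction. The same holds for the named genes PPDPF, IGFBP2, ZFAS1, HCFC1R1, CHCHD10, NAT14, BBLN, MARCKSL1, CENPE and FAM111B.

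Taking all treatments together against control, the 27 proteasome genes were lower in every case (median log2 difference -0.114, n = 9 against 2), with PSMD12 at -0.24 and PSMB3 at -0.22. Mitochondrial ribosomal protein genes (64 of 72, median -0.091), the microRNA machinery (16 of 22, -0.084), DNA replication genes (28 of 36, -0.061) and predicted miR-99/100 targets (23 of 31, -0.051) were lower as well. Camera's adjusted p was 7.42e-06, 5.48e-06, 0.00909, 0.025 and 0.00909 in that order, and each had adjusted p = 0.799 with an estimated correlation. Genes of every kind with a mean of 8 to 10 had a median of -0.059, and those of 10 to 12 had -0.071. The DNA replication median was therefore close to that of other genes of its level. With the replicate block the proteasome kept its call (adjusted p 3.67e-06), and the mitochondrial ribosome (median -0.054, 0.281) and predicted targets (-0.081, 0.101) lost theirs. With replicate 3 as a term in place of the block, 0 lists passed with an estimated correlation. The block also called mitotic genes (median -0.177, adjusted p 1.61e-10) and interferon response genes (-0.089, 0.00431) downward, and cytoplasmic ribosomal (0.138, 3.86e-08) and oxidative phosphorylation genes (0.131, 2.95e-06) upward. With an estimated correlation these had adjusted p = 0.813, and 0.882 for oxidative phosphorylation. Quantile normalization reduced the proteasome median to -0.064 (adjusted p 0.00914) and ended the calls of DNA replication (-0.01, 0.714), the microRNA machinery (-0.038, 0.527) and predicted targets (-0.021, 0.189). It also called tubulin and microtubule genes upward (0.057, 0.00914) and cytoplasmic ribosomal protein genes downward (-0.015, 0.0159), whereas among genes at or above the median level the latter were called upward (0.049, 0.00382). With an estimated correlation these had adjusted p = 0.883, 0.832 and 0.962. Among genes at or above the median level DNA replication (adjusted p 0.445) and the microRNA machinery (0.149) were not called, at unchanged medians of -0.061 and -0.084. DNA replication (median -0.13, adjusted p 2.65e-06) and the microRNA machinery (-0.134, 4.25e-05) had larger medians with the block than without, each with adjusted p = 0.813 with an estimated correlation. Without 1 array the proteasome moved between -0.171 and -0.08 and the mitochondrial ribosome between -0.15 and -0.034, and both kept their calls in 11 of 11 refits (highest adjusted p 0.013 and 0.0346, both without control replicate 2). The lowest medians were -0.125 for the microRNA machinery, -0.104 for DNA replication and -0.078 for the predicted targets. Leaving out control replicate 2 ended the calls of DNA replication (0.006, 0.841) and the microRNA machinery (-0.051, 0.131), and leaving out control replicate 1 that of the predicted targets (-0.06, 0.122). DNA replication was also lost without replicate 1 of miR-99a (-0.039, 0.0926), miR-100 (-0.05, 0.0907) or the combination (-0.046, 0.101), or without miR-100 replicate 2 (-0.046, 0.103).

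No gene was called by limma over all treatments, with 489 at an unadjusted p under 0.05 and a lowest adjusted p of 0.9999. The smallest p-values were those of PTK2B (0.25 ± 0.05), ENAM (0.27), DIRC1 (0.24), CD1E (0.22) and SMAD3-DT (0.28) upward and RPLP2 (-0.31 ± 0.07), CARNMT1 (-0.28), RPL27A (-0.42 ± 0.11), CMTR2 (-0.27) and FBXO5 (-0.24) downward. The arrays did not overlap in 575 genes, 2.91% against 3.64% by chance. The 489 genes with an unadjusted p under 0.05 were fewer than the share of 0.05 expected by chance. With the replicate block 3302 genes had such a p. With replicate 3 as a term 24 genes passed, 20 up and 4 down, and all 24 were among the 198 called in replicates 1 and 2 alone. Both fits give each gene the same difference here, because the control has no replicate 3 and each treatment has all replicate numbers. Only the error estimate differs, so the overlap is not independent support. Those 198 were 77 up and 121 down, and the term with quantile normalization gave 451 up and 100 down, so the balance of directions depends on the fit. The 24 genes included the lymphocyte receptor gene S1PR4 (0.44), ARF3 (0.43), the chromatin protein gene HMGA1 (0.42), CHCHD10 and NAT14 (0.41 each). Each of these named rises was lower in replicate 3 than in replicates 1 and 2 of the treated arrays (-0.67, -0.8, -0.8, -0.69 and -0.6 in that order). They may therefore reflect the difference that sets replicate 3 apart. The falls among the 24 were ZNF91 (-0.54 ± 0.11), ZNF302 (-0.35), the helicase gene DDX60 (-0.35) and PHB1 (-0.34). The replicate block called 507 genes, 178 up and 329 down.

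miR-100 and miR-99a, which have the same seed, were then compared with each other. ND6 was lower with miR-100 than with miR-99a, at a mean of 9.51 against 9.9 (log2 difference -0.39 ± 0.11, n = 3 each), and MIR17HG, the host gene of a cluster of growth-promoting microRNAs, had -0.3 ± 0.08. TNP2 (-0.23), AGT (-0.22) and SPANXB1 (-0.26) were the other smallest p-values downward, and LINC00314 (0.24), OR51E2 (0.25), FAM124B (0.24), TRIM42 (0.18) and MIR3681HG (0.17) those upward. Limma called 0 genes, with 194 at an unadjusted p under 0.05 and a lowest adjusted p of 1. The replicate block called ND6 (adjusted p 0.0479), and replicates 1 and 2 alone called FOLR1, a folate receptor gene (-0.73 ± 0.11, adjusted p 0.0303; -0.43 over all arrays), which was named after its value was seen. With replicate 3 as a term 0 genes passed. Over all arrays without a block none of the 28 lists differed, with reported targets at a median of -0.046 (adjusted p 0.359) and the proteasome at -0.032 (0.536). Without miR-100 replicate 3, 11 lists were called, against 0 over all arrays. The arrays did not overlap in 922 genes, 4.66% against 10% by chance. The 194 genes with an unadjusted p under 0.05 were fewer than the share of 0.05 expected by chance, as were the 363 with the replicate block. Without the block the median 95% half-width was 0.185 log2 units, so smaller differences between the oligos are not excluded.

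Whether the combination acted differently from the single oligos was asked at equal total oligo. Cytoplasmic ribosomal protein genes were higher with the combination than with the single oligos in 51 of 53 cases (median log2 difference 0.22, 0.138 without combination replicate 2 and 0.376 without combination replicate 3). RPS15 stood at 13.94 with both against 13.69 and 13.68 with each (0.25 ± 0.05) and RPS4X had 0.2 ± 0.06; RPS15 was the 1 member past the threshold adjusted over the list alone. Glycolysis and hypoxia genes were higher in 24 of 31 cases (median 0.069), with the glycolytic enzyme gene GAPDH at 0.22 ± 0.06 and ANKRD37 at 0.35 ± 0.16. Camera's adjusted p was 1.2e-30 and 0.00151, and adjusted p = 0.839 and 0.992 with an estimated correlation. Averaged over its genes, the ribosomal list stood at 13.45 ± 0.21 with the combination (SD, n = 3) and 13.25 ± 0.09 with the single oligos (n = 6), a difference of 0.196 with a 2-sided exact permutation p of 0.0714 over 84 splits. Taken as the median of its genes instead, the difference was 0.239 (13.98 ± 0.21 against 13.74 ± 0.1) with a 2-sided exact permutation p of 0.0476. Within replicate numbers the combination was highest in 3 of 3, with an exact permutation p of 0.037, the smallest that 27 splits allow. These exact tests were not among those fixed beforehand. They were run on this list alone of the 28, the one with the lowest camera p, and are not adjusted for that choice. After quantile normalization the list's difference was 0.004 (exact permutation p 0.571), but of the 95 genes with a mean of 13 or more only 49 are not ribosomal protein genes, so that step sets the list to nearly the same level on every array whether or not it rose. The glycolysis call was lost after quantile normalization (median 0.041, adjusted p 0.0692) and without miR-100 replicate 1 (0.056, 0.0822), and without other single arrays the median reached 0.099. Among genes at or above the median level oxidative phosphorylation (median 0.071, adjusted p 0.000665), B-lineage markers (0.072, 0.000665), cholesterol synthesis (0.049, 0.00238) and the unfolded protein response (0.043, 0.0112) were called upward too, with adjusted p = 0.941, 0.829, 0.66 and 0.941 with an estimated correlation. With the replicate block 7 lists were called, with oxidative phosphorylation higher (adjusted p 9.99e-07) and mitotic genes lower (0.0184), both with adjusted p = 0.955 with an estimated correlation.

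**Figure D3:**
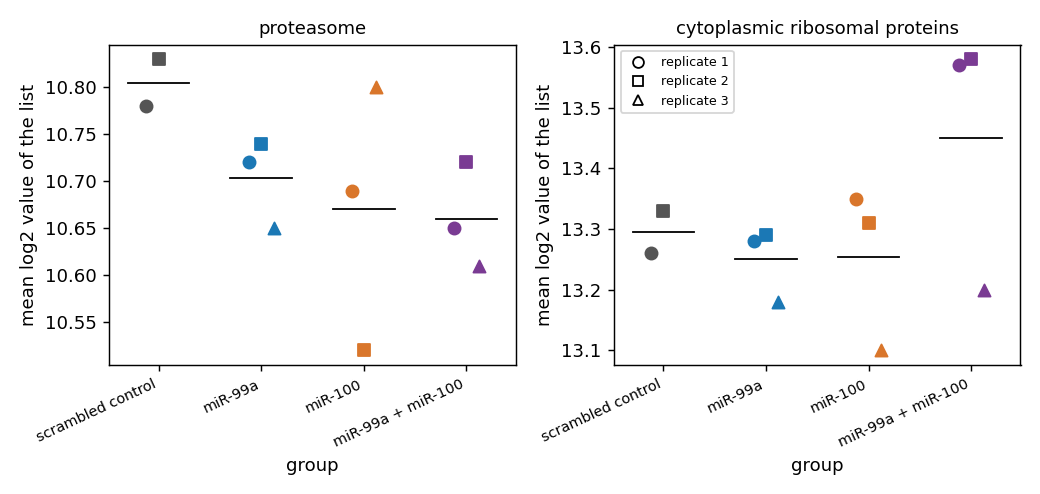
Mean log2 expression of the proteasome and the cytoplasmic ribosomal protein lists in each of the 11 arrays, with bars at group means. The proteasome mean is 10.8 in control and 10.66 to 10.7 in the treated groups, and the ribosomal mean is 13.45 with both oligos against 13.25 with each alone.

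No gene differed between the combination and the single oligos by limma, with 451 at an unadjusted p under 0.05 and a lowest adjusted p of 0.9998. The smallest p-values upward were those of SIX3 (0.29 ± 0.06), RPS15, LOC100288175 (0.22), the RNA-binding protein gene YBX1 (0.26 ± 0.06) and ZNF486 (0.24), and downward those of NCAM2 (-0.22), CEACAM3 (-0.19), ACTL6A (-0.22 ± 0.06), PPFIBP1 (-0.26 ± 0.07) and ARHGEF38 (-0.21). The replicate block called 1 gene, ANPEP, which encodes aminopeptidase N: it stood at 11.92 with both and at 11.43 and 11.55 with miR-99a and miR-100 (0.43 ± 0.08, adjusted p 0.0191), and was named after its value was seen. With replicate 3 as a term, and in replicates 1 and 2 alone, 0 genes passed. The arrays did not overlap in 315 genes, 1.59% against 2.38% by chance. The 451 genes with an unadjusted p under 0.05 were fewer than the share of 0.05 expected by chance. With the replicate block 1097 genes had such a p.

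How far the 3 treatments resembled each other was measured against the likeness that shared control arrays give by themselves. Across genes, which are not independent replicates, the log2 differences from control correlated at r = 0.711 (Spearman's rho 0.689) between miR-99a and miR-100, 0.658 (0.631) between miR-99a and both, and 0.714 (0.688) between miR-100 and both. Simulated unchanged groups against the same controls gave mean correlations of 0.6 to 0.601 and at most 0.625. The covariances went the other way: 0.00464, 0.00526 and 0.00611 against 0.0104, 0.0104 and 0.0103 in the simulations, which drew on a spread that includes replicate 3. The sign was the same in 75.1%, 72.3% and 74.8% of genes. The treatments also share replicate numbers, which the simulations do not carry.

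Lists that did not pass in any comparison with control over all arrays, without a block, are given for the combination. B-lineage markers (28 genes, median log2 difference 0.036, adjusted p 0.578; 0.042 and 0.0479 among genes at or above the median level, and 0.921 with an estimated correlation) included RAG2 at -0.25 ± 0.08 and MME at -0.21 ± 0.14. Markers of other cell types were not called: T and NK cells -0.021 (adjusted p 0.56), myeloid cells 0.015 (0.828), erythroid cells and platelets -0.012 (0.966) and fibroblasts and epithelium 0.015 (0.56). Reported miR-125b targets (37 genes, median -0.016, adjusted p 0.56) included ETS1 at -0.26 ± 0.12. The mTOR and PI3K pathway had -0.048 (0.828), with TSC2 at 0.17 ± 0.08, and the glucocorticoid response -0.003 (0.8), with DUSP1 at 0.23 ± 0.09. The BCL2 family had -0.028 (0.56), with BIRC2 at -0.28 ± 0.1, p53 targets -0.075 (0.0559), with AEN at -0.23 ± 0.08, and the type I interferon response -0.042 (0.0828; -0.13 and 0.00317 with the replicate block, and 0.784 with an estimated correlation), with IFI44 at -0.24 ± 0.09 and ISG15 at -0.27 ± 0.11. Cholesterol synthesis had -0.016 (0.855), the NF-kB and TNF response 0.02 (0.449), heat shock proteins -0.03 (0.811), with HSPA4L at 0.2 ± 0.07, and replication-dependent histones 0.029 (0.828).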

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

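The tests of the ribosomal protein genes against their intensity and against added control RNA, and the counting of splits by genes, were chosen only after the result was seen, while the counting of splits by lists was planned. The exact permutation tests of the ribosomal list were not planned either.

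Cytoplasmic ribosomal protein genes had a median log2 difference of 0.22 between the combination and the single oligos, with 51 of 53 genes higher, among them RPS15 and RPS4X. Against a specific rise, the 49 other genes with a mean of 13 or more had a median of 0.177 (quartiles 0.141 to 0.201), in line with a difference between arrays at high intensity left by the normalization. Beyond level-matched other genes the mean gap was 0.035 (SE 0.024, 45 ribosomal genes against 18 distinct others), which does not settle whether ribosomal genes rose on their own. Added control RNA rows were 0.209 higher in the combination but in 2 of 3 replicate numbers only (2-sided exact permutation p 0.31), so brighter hybridization could be neither shown nor excluded. A biological effect of the combination on ribosomal protein genes was not tested apart from these array differences and stays open.

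When the 9 treated arrays were split into 3 and 6 in all 84 ways, 84 gave at least as many called genes as the real split, which gave 0, so this count carries no information. The split with the most, 6073 genes, put the 3 replicate 3 arrays together and reflects the structure of the samples. For lists, 69 of 84 splits gave at least the 2 calls of the real split, and the highest other was 16. Among the 27 splits with an array of each number, 16 gave as many.

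Glycolysis and hypoxia genes, GAPDH among them, had a median log2 difference of 0.069 between the combination and the single oligos. Camera's call was lost after quantile normalization and without miR-100 replicate 1 (median 0.056, adjusted p 0.0822). Genes of every kind had medians of -0.027 at a mean of 8 to 10, 0.01 at 10 to 12, 0.108 at 12 to 13 and 0.196 at 13 and over. How far the brighter members of the list share this difference was not tested.

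Added control RNA rows had a mean log2 difference of 0.238 between the combination (13.5 ± 0.39, SD, n = 3) and control (13.27 ± 0.16, n = 2). Control probe sets later in the table, from the human ones on, look shifted against their names; these rows stand before them, and their identity was not tested further.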

How the results depend on the processing

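Among gene counts, trend and robust moderation, the filter, the mean of probe sets, leaving out cross-matching probe sets, quantile normalization, centring, the compared groups alone, the 2-fold minimum, treat and leaving out any 1 array all left 0 genes. The replicate block gave 5 genes for miR-99a, 7 for miR-100, 863 for both, 507 for any treatment, 1 between the single oligos and 1 for the combination against them. Chosen after the components were seen, the replicate 3 term gave 443 for both and 24 for any treatment, and replicates 1 and 2 alone gave 290, 198 and 1 between the single oligos. The term with quantile normalization gave 60, 158, 600 and 551. The cause was not tested.

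Among list counts, an estimated correlation and fry left 0 lists in each comparison. For the combination against the single oligos the replicate block and the replicate 3 term each gave 7, replicates 1 and 2 alone 6, the filter 6 and quantile normalization 0. Replicates 1 and 2 alone gave 10 for miR-100 and 17 between the single oligos. The filter left 3 for miR-99a and 3 for miR-100, and quantile normalization 2 and 3, with 1 for both oligos. Leaving out 1 array moved the counts between 2 and 9 for miR-99a (without control replicate 2 and control replicate 1), 1 and 12 for miR-100 (miR-100 replicate 2 and control replicate 1), 5 and 8 for both (combination replicate 1 and miR-99a replicate 3), 4 and 11 for any treatment (control replicate 2 and control replicate 1), 0 and 11 between the single oligos (highest without miR-100 replicate 3) and 2 and 6 for the combination against them (highest without miR-100 replicate 2).

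Some lists changed direction, by their median or by camera. Under the replicate block and the replicate 3 term the medians for miR-99a were 0.066 for cytoplasmic ribosomal proteins and 0.102 for oxidative phosphorylation, and 0.072 for cytoplasmic ribosomal proteins with miR-100. Replicates 1 and 2 alone gave 0.011 for mitochondrial ribosomal proteins and 0.129 for oxidative phosphorylation with miR-99a and 0.072 for cytoplasmic ribosomal proteins with miR-100. Quantile normalization gave -0.004 for the ATF4 and unfolded protein response with miR-100, where only camera's direction turned (adjusted p 0.923), and -0.011 for both and -0.015 for any treatment for cytoplasmic ribosomal proteins. Leaving out 1 array moved oxidative phosphorylation with miR-99a from -0.187 to 0.129, and cytoplasmic ribosomal proteins with miR-100 from -0.078 to 0.072.

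The likeness of miR-99a and miR-100, miR-99a and both, and miR-100 and both was 0.782, 0.715 and 0.757 with the filter and 0.67, 0.636 and 0.67 after quantile normalization. Without single arrays it lay at 0.484 to 0.825, 0.463 to 0.765 and 0.496 to 0.801, highest without control replicate 1 and lowest without miR-99a replicate 3, combination replicate 3 and miR-100 replicate 2. Of 3197 values for named genes in the other fits, 3020 did not change sign and were not called, and 37 did not change sign and were called. A further 140 changed sign, and 0 changed sign with a call or with both values beyond their SE. The size of a value was not compared. With 0 genes called in the main fit no call could be lost, so these counts do not show that the values were stable. Seed sites were planned but not run.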

Other observations

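Averaged over the treatments, replicate 3 differed from replicates 1 and 2 in many genes; whether the difference was equal in each treatment was not tested. Chosen after the values were seen, the genes that separated it most from replicates 1 and 2 were TMEM167A (log2 difference -0.99 ± 0.07), RUNX1-IT1 (0.93 ± 0.07), GPR160 (-1.01 ± 0.07), the AP-1 transcription factor gene JUND (-0.97 ± 0.07) and the Mediator subunit gene MED21 (-0.96 ± 0.07; SE, n = 3 against 6, adjusted p 9.77e-15 to 3.43e-14). Of 19775 genes 5794 (29.3%) were called, 3382 higher and 2412 lower. Oxidative phosphorylation genes were called lower in 43 of 59 cases and higher in 10, with NDUFB5 at -0.84, COX7A2 at -0.77, and COX7B and ATP5F1E at -0.74. Mitotic genes were called higher in 23 of 34 cases and lower in 4. The kinetochore genes CENPE at 0.92 ± 0.09 and CENPF at 0.81 ± 0.08, ASPM at 0.86 and TOP2A at 0.52 were higher. The cell cycle kinase gene CDK1 (-0.61) and the checkpoint gene MAD2L1 (-0.63) were lower.

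Other lists moved along the same difference. Counting genes past the threshold, DNA replication genes were called higher in 23 of 36 cases and lower in 3 (median 0.208, camera's adjusted p 9.68e-05). The counts were 10 and 0 of 22 for the microRNA machinery (0.154, 0.00537) and 14 and 3 of 37 for tubulin and microtubule genes (0.115, 0.00532). Interferon response genes had 15 and 4 of 35 (0.076, 0.0238). Cytoplasmic ribosomal protein genes were called lower in 35 of 53 cases and higher in 2. The counts were 32 and 17 of 72 for mitochondrial ribosomal protein genes (median -0.116, camera's adjusted p 6.85e-05) and 11 and 3 of 23 for BCL2 family genes (-0.114, 0.00698). Histones had 9 and 3 of 23 (-0.135, 0.0238). With an estimated correlation none passed (lowest adjusted p = 0.789).

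The tests of the proteasome, of the replicate 3 difference and of zinc finger genes were chosen only after the result was seen; the removal of the trend on gene length and the splits by lists were planned.

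Proteasome genes were lower in all treatments, with a median log2 difference of -0.114 against control over all 27 genes, and of 10000 random lists matched on mean expression 0.16% had a median as low (matched median -0.065, lowest -0.129), which argues against an effect on all genes of that level, although random lists ignore co-regulation and understate chance. With replicate 3 as a term the median was -0.13, but quantile normalization reduced it to -0.064, so part of it depends on the normalization. The list was not called between replicate 3 and the others (median 0.086, camera's adjusted p 0.834, with 10 genes called up and 9 down). Of the splits, 3 of 55 that part the 11 arrays into 2 and 9 gave a median as low, but these ignore the replicate numbers, and the lowest, -0.189, set control replicate 2 and miR-100 replicate 3 apart. When 1 array of replicate 1 and 1 of replicate 2 were set against the others of those numbers, the control pair was the lowest of 16 (-0.13, against -0.088 for the next), with a 1-sided exact p of 0.0625, the smallest these splits allow, so chance is not excluded. An effect of the oligos on the proteasome was not tested apart from these and stays open.

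With replicate 3 as a term, mitotic and DNA replication genes were lower and oxidative phosphorylation genes higher in treated arrays, and over 9888 genes the difference of the combination from control in replicates 1 and 2 correlated at -0.695 (Spearman's rho -0.657) with that of replicate 3 from replicates 1 and 2 of the single oligos, which share no array with it. Of the 443 genes called for the combination with the term, 429 (96.8%) had opposite signs on this difference. Of the 9888 genes, those at or above the median level, 75.6% had opposite signs, taken from the combination minus control in replicates 1 and 2. The 2 shares rest on different genes and fits, so they are only roughly comparable. In the fit with the term, the replicate 3 difference of the single oligos enters the combination's estimate with a minus sign. The share of 96.8% is thus partly built in, which does not apply to the correlation. The calls may therefore reflect where the control arrays lie along the difference that sets replicate 3 apart. Whether that difference arose in the cells or from RNA quality was not tested and stays open. The trend on genomic gene length was removed from the difference of all treatments from control, fitted with the term. This changed the mitotic median from -0.177 to -0.156, which argues against that length as the source of the shift of this 1 list. The difference of replicate 3 itself was not tested for gene length. Transcript length was not tested at all, although genes with long transcripts such as AKAP9 (0.92 ± 0.08) and SYNE2 (0.89 ± 0.08) were among those higher in replicate 3.

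ZNF91 and ZNF302 fell with the term. The 90 zinc finger genes of chromosome 19 with a mean log2 above 7 were examined only in the fit without the term. There they had a median of -0.036 in treated arrays against -0.046 for 7914 other genes above that level. In that fit they did not fall further as a group than other genes, and with the term the group was not tested. Between miR-100 and miR-99a, 10 of 10 splits gave at least as many called genes and 10 of 10 as many lists as the real split, which had 0 of each; other splits reached 15 lists and 0 genes. With 10 splits and a real count of 0 nothing can be read from them.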
